A study of Homo sapiens with 24 samples.

How the data were processed

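Messenger RNA was measured in 24 libraries of the glioblastoma lines U87 MG and LN229 and their temozolomide-resistant derivatives U87-R and LN229-R, treated with DMSO or 50 µM STM2457 for 96 h, with 3 replicates per group. Per the labels' protocols, U87 cells grew in EMEM with 10% serum and were prepared with a stranded TruSeq mRNA kit, and LN229 cells grew in DMEM with 5% serum and were prepared with a Watchmaker mRNA kit, so kit and medium differed with the background. The labels do not say that replicates are separate cultures. If they are not, the p-values measure only the spread between these samples.

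The deposited values are signal in the form of normalized counts that the authors made. Per the submitters' processing notes, the programs were Trimmomatic 0.39, STAR 2.7.11a, Salmon 1.4.0 and DESeq2 on GRCh38 (hg38), without their order or settings. The values came in 6 tables of 6 libraries, each normalized on its own with factors that differ between genes, so whole read counts could not be recovered and tests that need them were not used. The tables listed 22452 to 22723 genes in the LN229 family and 28099 to 28669 in the U87 family, from different annotation releases, and were joined on Ensembl identifiers without version. Estimated reads per library, a rough figure, were 20300000 to 29100000 in the U87 family and 17900000 to 30700000 in the LN229 family. Correlations between replicates were 0.966 to 0.988.

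Within each table, log2 of the value plus a pseudocount of 1 was fitted with limma 3.58.1 and a trend of the variance on the mean, for genes with a mean of at least 10. A gene passed, and was said to rise, fall or change, with an adjusted p (Benjamini and Hochberg) under 0.05. The comparisons were U87-R against U87 MG and LN229-R against LN229 in DMSO, and STM2457 against DMSO in each line. Differences between effects were tested in a joint fit of the tables. Values of groups listed at 0 depend on the pseudocount and bound nothing. Overlaps were tested with Fisher's exact test, two-sided, over genes tested in both comparisons, with the number expected from the counts in each direction. Because the same controls enter resistance and drug effects, their correlation was set against 100 simulations without effects. The fits ran in R 4.3.3, and plots and correlations used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9.

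Gene lists were tested with camera, with a fixed correlation of 0.01 between genes and at least 5 measured members, and again with a correlation estimated from each list. The 27 lists covered m6A writers, erasers and readers, mismatch repair, base excision repair, homologous recombination, p53 targets, S phase, G2 and M phase, interferon, ATF4 targets, the unfolded protein response, cholesterol, hypoxia, oxidative phosphorylation, ribosomal proteins, matrix, inflammation, immediate early genes, glioma stem genes, efflux transporters, NRF2 targets, histones, mitochondrially encoded mRNAs and cell type markers. The lists, comparisons, thresholds, alternatives and rule for named genes were chosen before the data were examined. The rule named, per comparison, the 6 largest rises and 6 largest falls among genes that passed with a mean of at least 100 and no overlap between groups, which chance gives in 10% of genes for 3 against 3, leaving out unnamed loci, pseudogenes and antisense genes. It also named a panel of genes of m6A, DNA repair, p53, drug efflux and glial identity, and the members of passing lists with the lowest adjusted p. For overlaps it named the genes with the largest changes. Some genes that this rule selects, in the panel, the largest changes and the lists, are not reported here. Other genes of the panel with no value given in a paragraph did not pass there or were below the filter.

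Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, equal totals, equal upper quartiles, no variance trend, the replicate as a block, separate fits for differences, an adjusted p under 0.01, a log2 change of at least 1, fry instead of camera, and leaving out each replicate, with the range given for medians of passing lists that this moved at least 1.5 times. The LN229 names exchanged in either kind of table and the STM2457 tests between backgrounds were added after the data were examined. The block is given beside results in comparisons where all like-numbered libraries correlated above 0.1. The counts with the block had been seen before those correlations.

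The steps were tested on simulated data built on these libraries, with 50 changed genes of each size in 5 simulations. At a log2 change of 1, 39.6% of changed genes were recovered in the U87 resistance comparison and 57.2% in that of LN229, and 50, 49.2, 50 and 42.8% in the STM2457 comparisons of U87 MG, U87-R, LN229 and LN229-R. At a log2 change of 2, 72.4 to 82% were recovered, and false calls averaged 4.4 to 6.6 per simulation. Tests of a difference, in 1 simulation each, recovered 35 to 43% at 1 and 55 to 75% at 2 with 3 to 10 false calls, the 10 in LN229-R against LN229. Transcript models of GENCODE release 29 gave exon junctions and lengths.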

Results

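Polyadenylated RNA was sequenced in 24 libraries from 4 human glioma cell lines. U87 MG and LN229 are established glioblastoma lines. U87-R and LN229-R are derivatives resistant to temozolomide, an alkylating drug, and their medium held 50 µM of it. The parental lines had none, so differences called resistance here are not separated from the drug in the medium. Each line received the solvent DMSO or 50 µM STM2457 for 96 h, which makes 8 groups of 3 replicates. STM2457 inhibits METTL3, the catalytic subunit of the complex that writes m6A on mRNA. The normalized counts of a library summed to 21232924 to 25349361 in the U87 family and to 24101385 to 28716587 in the LN229 family. Group values are means of normalized counts ± SD with n = 3, and changes are log2 changes with their standard error (SE).

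The names of the LN229 control libraries conflicted between the deposited tables. Every DMSO library stood in a table of parental against resistant cells and in a table of DMSO against STM2457. In the U87 family, all 6 columns of the first table were closest to the like-named library of the second, with an SD of the log2 ratio across genes of 0.0576 to 0.0595 over at least 10016 genes with a mean of at least 200. In the LN229 family, all 6 columns were closest to the library with the same replicate number and the other line's name. The SD was 0.0585 to 0.0618 for that match, against 0.361 to 0.415 for the like-named library, over at least 11168 genes. The plot of MGMT by table shows the conflict in 1 gene. In LN229 cells the direction of every difference between resistant and parental cells therefore depends on which table is right, and it is given here for the libraries as labelled. The names of the STM2457 tables do not affect the direction of a drug effect, but they decide which LN229 line it belongs to.

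**Figure D1:**
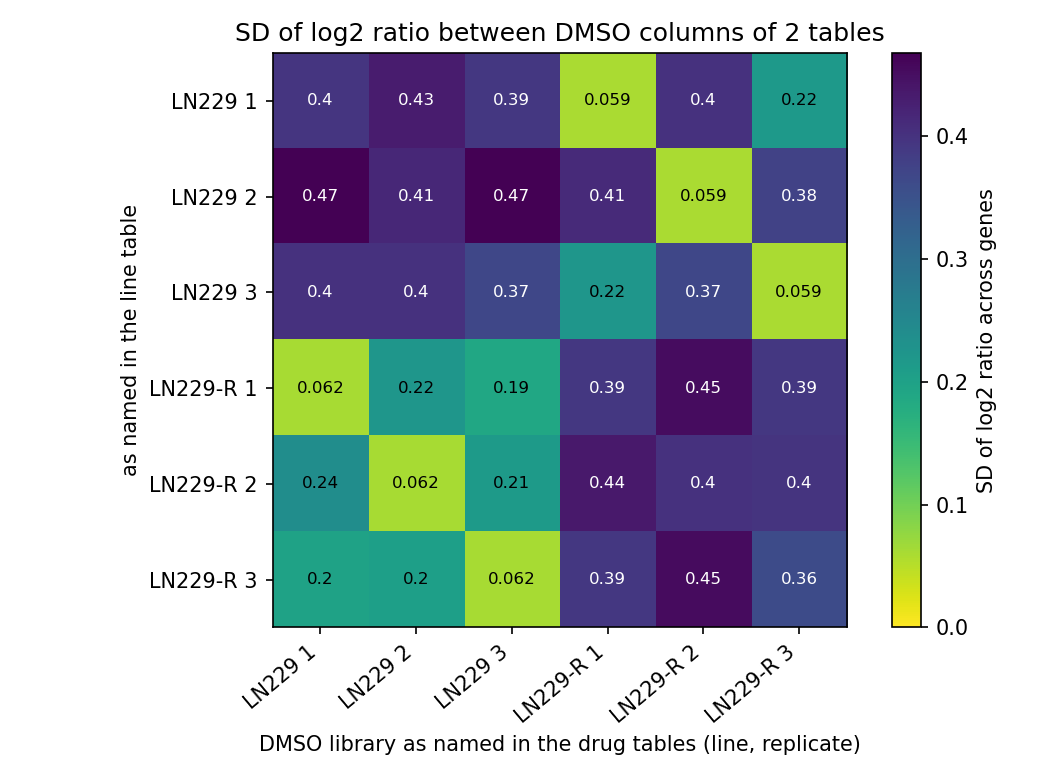
Heat map of the SD of the log2 ratio between each DMSO column of the parental against resistant tables and each DMSO column of the DMSO against STM2457 tables, over genes with a mean of at least 200. Small values mark the same library, and they join columns with different names at 0.0585 to 0.0618.

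The comparison of U87-R with U87 MG in DMSO asks which RNAs differ between resistant and parental cells. MGMT, which encodes the enzyme that removes methyl groups from guanine in DNA, had 1043 ± 309 normalized counts in U87-R and 0.726 ± 1.26 in U87 MG (SD, n = 3; adjusted p = 5.5e-05). MGMT is ENSG00000170430, on chromosome 10 from 129467241 to 129770983 of GRCh38. CHFR, a ubiquitin ligase of a mitotic checkpoint, had 208.7 ± 119 in U87-R against 1.47 ± 2.54, and the cancer-testis gene MAGEA11 had 201.5 ± 71.3 against 1.90 ± 1.22. The zinc finger gene ZNF83 (301.3 ± 71.0 against 5.21 ± 6.15) was also among the largest rises, as was POTEM, a member of a family of near-identical copies for which reads may be assigned to the wrong copy. Among the largest falls were LDOC1 (-6.29, SE 0.73), ACTL8 (-4.20, SE 0.42), the calcium channel subunit gene CACNG8 (-3.05, SE 0.32), the collagen-binding integrin gene ITGA11 (-2.67, SE 0.33) and LIMCH1 (-2.51, SE 0.49). METTL3 had a log2 change of 0.49 (SE 0.12) that missed the threshold, with an adjusted p of 0.052. The mismatch repair genes MSH6 and PMS2 had log2 changes of -0.04 and -0.17 and did not pass.

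Of 16306 genes tested with limma in this comparison, 697 changed, 510 higher and 187 lower in U87-R, with equal totals 456 and 184, and with equal upper quartiles 506 and 182. Among the lists fixed before the data were examined, 6 of 24 passed the camera test. Hypoxia and glycolysis genes were shifted up, with a median log2 change of 0.17 over 30 members (camera adjusted p = 0.00035). EGLN3, a prolyl hydroxylase induced in hypoxia, rose by 2.56 (SE 0.33), and 29 members did not pass, while 3 members rose adjusted over the list alone. None of the 13 mitochondrially encoded mRNAs passed alone, although their median was 0.29 (adjusted p = 0.00035). In the unfolded protein response list, with a median of 0.15, CRELD2 (0.71, SE 0.09) and SDF2L1 (0.61, SE 0.12) rose and 23 members did not pass, while 5 rose adjusted over the list alone (adjusted p = 0.0017). The type I interferon list had a median of 0.18, and BST2 (2.55, SE 0.37) and IRF9 (0.97, SE 0.22) rose among 35 members, or 3 adjusted over the list alone (adjusted p = 0.033). S phase genes were shifted down with a median of -0.18, and the histone mRNA-binding gene SLBP fell by 0.63 among 28 members, also when adjusted over the list alone (adjusted p = 0.0014). The inflammatory list was shifted down with a median of -0.17 over 28 members (adjusted p = 0.031). In that list the prostaglandin synthase gene PTGS2 fell by 1.4 while TNFAIP2 (2.14, SE 0.17) and ICAM1 (0.78, SE 0.15) rose, and 2 rose and 7 fell adjusted over the list alone. The cholesterol list (median 0.01, mean 0.08, test down) did not pass.

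Several of these calls were lost when 1 library was left out. A fit with fewer libraries has less power, so a lost call need not rest on the library left out. The number of changed genes was 315 without replicate 2 of U87-R, 420 without its replicate 3 and 330 without replicate 2 of U87 MG. LIMCH1 lost its call without replicate 2 of U87-R or replicate 1 or 3 of U87 MG (highest adjusted p 0.071). SDF2L1 lost its call without any 1 of the 6 libraries (0.079), SLBP, IRF9 and ICAM1 without any 1 except replicate 1 of U87 MG (0.13, 0.17 and 0.11), and PTGS2 without replicate 2 or 3 of either line (0.085). The S phase list lost its call without replicate 3 of U87 MG (adjusted p = 0.09). The interferon list lost it without replicate 3 of U87 MG or replicate 1 or 2 of U87-R (highest adjusted p 0.18), and the inflammatory list without replicate 2 or 3 of U87 MG or replicate 1 or 2 of U87-R (0.44). Without replicate 1 of U87 MG, 10 lists passed. Without 1 library the median was 0.06 to 0.25 for the hypoxia, -0.29 to -0.08 for the S phase, 0.03 to 0.26 for the interferon and -0.49 to -0.08 for the inflammatory list.

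The same question in the LN229 family was put to the libraries labelled LN229-R and LN229. MGMT was listed at 0 in all 3 libraries labelled LN229-R and had 198.6 ± 8.91 normalized counts in those labelled LN229. In the table of DMSO against STM2457 the libraries labelled LN229-R had 195.5 ± 8.38 in DMSO. MAGEA11 (ENSG00000185247, chromosome X, 149688193 to 149717268) had 278.3 ± 3.44 in the libraries labelled LN229-R against 0.965 ± 1.24 (SD, n = 3; adjusted p = 0.00013). The guidance ligand gene SLIT3 had 378.8 ± 33.9 against 0.241 ± 0.418, TMPRSS15 had 312.5 ± 44.5 against 0.563 ± 0.490, PGAP4 had 226.8 ± 40.7 against 0.336 ± 0.582, and MAGEA10 had 294.2 ± 21.8 against 2.16 ± 2.24. TUBA3C had 680.5 ± 2.43 and was listed at 0 in the libraries labelled LN229, in a gene with near-identical copies. Lower in the libraries labelled LN229-R were the scavenger receptor gene SCARA5 (-2.88, SE 0.46), the cartilage proteoglycan gene ACAN (-2.57, SE 0.19), the kinase gene PAK3 (-2.48, SE 0.35), COL9A1 (-2.26, SE 0.39), FGFBP2 (-2.0, SE 0.31) and the BMP antagonist gene CHRDL1 (-1.98, SE 0.11). METTL3 had a log2 change of 0.06 (SE 0.08), and MSH6 and PMS2 had 0.15 and -0.19, none of which passed.

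In this comparison 1585 of 17136 genes changed, 959 higher and 626 lower in the libraries labelled LN229-R. With equal totals 1188 were higher and 471 lower, and with equal upper quartiles 979 and 600. The replicate numbers paired these libraries, with correlations of 0.114 to 0.204 between like-numbered libraries, and a fit with the replicate as a block called 2600. Of 24 lists, 8 passed, and at least as many did in 6 of 10 splits. Replication-dependent histone genes had a median of 0.77 in the libraries labelled LN229-R, and 6 of 14 members rose, also when adjusted over the list alone, among them H2BC12 (1.04, SE 0.12) and H2BC21 (1.49, SE 0.23; camera adjusted p = 0.00015, and adjusted p = 0.23 with an estimated correlation). The S phase list had a median of 0.36, and the licensing genes MCM2 (1.15, SE 0.23) and CDT1 (0.65, SE 0.14) rose among 28 members, also when adjusted over the list alone (adjusted p = 0.00022, and adjusted p = 0.9 with an estimated correlation). No member of the G2 and M phase list passed alone, and its median was 0.24 (adjusted p = 0.0078, and adjusted p = 0.9 with an estimated correlation). In the list of glutathione and NRF2 targets, with a median of 0.30, 6 of 25 members rose and 1 fell, or 10 and 1 adjusted over the list alone, with the aldose reductase gene AKR1B1 at 0.65 (SE 0.10) and the cystine carrier gene SLC7A11 at -0.99 (SE 0.17; for the list, camera adjusted p = 0.001, and adjusted p = 0.54 with an estimated correlation). The inflammatory list had a median of 0.47, and 4 of 20 members rose and 1 fell, or 9 and 1 adjusted over the list alone, with TNFAIP2 at 4.52 (SE 0.27), CCL2 at 1.81 (SE 0.21) and LIF at -1.31 (SE 0.12; for the list, camera adjusted p = 0.0053, and adjusted p = 0.64 with an estimated correlation). Of 34 interferon response genes 3 rose and 1 fell, or 9 and 1 adjusted over the list alone, with a median of 0.25 (adjusted p = 0.011, and adjusted p = 0.64 with an estimated correlation). PARP9 was at 1.16 (SE 0.10), PARP14 at 0.82 (SE 0.12) and BST2 at -0.82 (SE 0.15). Of 11 drug efflux transporter genes ABCC3 (3.36, SE 0.35) and ABCA1 (0.85, SE 0.19) rose, also when adjusted over the list alone, with a median of 0.12 (adjusted p = 0.045, and adjusted p = 0.51 with an estimated correlation). Unfolded protein response genes were lower, with a median of -0.21, 6 of 25 members falling, or 7 adjusted over the list alone, PDIA6 at -0.72 (SE 0.10) and CRELD2 at -0.56 (SE 0.09; for the list, camera adjusted p = 2.5e-05, and adjusted p = 0.51 with an estimated correlation).

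With the replicate block, homologous recombination and Fanconi anemia genes (adjusted p = 0.036) and p53 targets (adjusted p = 0.034) passed as well. Median, mean and test differed in sign for base excision repair (0.01, -0.29, up), for glioma stem and astrocyte genes (-0.05, 0.24, down) and for oligodendrocyte lineage markers (-0.10, 0.14, down), none of which passed. The count of changed genes was 606, 683 and 534 without replicate 1, 2 or 3 of the libraries labelled LN229-R, and 1039, 3262 and 906 without replicate 1, 2 or 3 of those labelled LN229. COL9A1 lost its call without replicate 1 or 3 labelled LN229-R (highest adjusted p 0.059), SLC7A11 without replicate 1 (0.054), BST2 without replicate 2 or 3 (0.075), CRELD2 without replicate 3 (0.057), and MCM2 and CDT1 without any 1 of the 3 (0.085 and 0.097). ABCA1 lost its call without replicate 1 or 3 of either line (0.10). Replicate 2 labelled LN229 stood apart, with 3.28% of normalized counts in ribosomal protein genes against 2.01 and 2.14% in replicates 1 and 3. Without it the S phase median was 0.09 (adjusted p = 0.16), the G2 and M phase median was -0.07 (adjusted p = 0.46), and the ribosomal protein median was 0.33 (adjusted p = 2.2e-15) instead of 0.10. The homologous recombination list passed without replicate 1 or 3 labelled LN229 or 2 labelled LN229-R (lowest adjusted p 0.0056). Medians were 0.05 to 0.32 for the transporter, 0.31 to 0.58 for the inflammatory and 0.19 to 0.30 for the NRF2 list. The interferon list lost its call without replicate 1 labelled LN229-R (adjusted p = 0.051), and the transporter list without replicate 1 or 3 labelled LN229 or replicate 2 labelled LN229-R (highest adjusted p 0.069).

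The comparison of STM2457 with DMSO asks which RNAs change when METTL3 is inhibited, and it was made in each line. In U87 MG, the tight junction gene CLDN14 rose by 3.22 (SE 0.48), the vacuolar proton pump subunit gene ATP6V0D2 by 2.99 (SE 0.31), the thiomorpholine-carboxylate dehydrogenase gene CRYM by 2.77 (SE 0.31), the neuropeptide gene NMB by 2.75 (SE 0.36), KLHL38 by 2.69 (SE 0.33) and the cytokine gene IL24 by 2.58 (SE 0.42). The collagen gene COL1A2 (ENSG00000164692, chromosome 7, 94394895 to 94431227) went from 25410 ± 10800 in DMSO to 4009 ± 1340 after STM2457 (SD, n = 3; adjusted p = 0.0022). ITGA11 was at -3.73 (SE 0.78), the adhesion gene VCAM1 at -3.67 (SE 0.63), the kinase gene CAMK2A at -2.89 (SE 0.28), PPL at -2.84 (SE 0.59) and HMCN2 at -2.65 (SE 0.47). METTL3 had a log2 change of 0.08 (SE 0.12; adjusted p = 0.7), and the m6A reader gene YTHDF2 rose by 0.74 (SE 0.09; adjusted p = 0.002). PMS2 rose by 0.35 (SE 0.10; adjusted p = 0.049), and MSH6, at -0.05, did not pass. MGMT stayed at 0.618 ± 1.07 in DMSO and 0.388 ± 0.672 after STM2457.

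In U87 MG 2228 of 16407 genes changed, 1289 higher and 939 lower. With every library scaled to the same total 1662 were higher and 760 lower, and with equal upper quartiles 1163 and 1136. Of 24 lists, 12 passed. Hypoxia and glycolysis genes fell together, 21 of 30 members, or 26 adjusted over the list alone, with a median of -0.61 (camera adjusted p = 6e-14, and adjusted p = 0.53 with an estimated correlation). The glucose carrier gene SLC2A1 was at -1.26 (SE 0.13) and PFKFB4 at -1.35 (SE 0.14). In the G2 and M phase list 12 of 32 members fell, while 1 rose and 21 fell adjusted over the list alone, with a median of -0.55 (adjusted p = 3.1e-09, and adjusted p = 0.53 with an estimated correlation). The topoisomerase gene TOP2A was at -0.74 (SE 0.10) and NDC80 at -0.83 (SE 0.12). In the S phase list 5 of 28 fell and 1 rose, or 9 and 1 adjusted over the list alone, with a median of -0.25 (adjusted p = 0.00049, and adjusted p = 0.61 with an estimated correlation). TYMS was at -1.20 (SE 0.16) and RRM2 at -1.44 (SE 0.19). Of 41 matrix and mesenchymal genes 13 fell and 4 rose, or 18 and 6 adjusted over the list alone, with a median of -0.50 (adjusted p = 0.0051, and adjusted p = 0.6 with an estimated correlation). TIMP3 was at -2.04 (SE 0.22) and COL1A1 at -2.06 (SE 0.24). Among 29 p53 targets 9 rose, while 13 rose and 2 fell adjusted over the list alone, with a median of 0.19 (adjusted p = 0.0059, and adjusted p = 0.6 with an estimated correlation). TP53I3 was at 1.30 (SE 0.17) and PHLDA3 at 0.72 (SE 0.10). Among 24 m6A genes 6 rose, while 7 rose and 1 fell adjusted over the list alone, with a median of 0.23 (adjusted p = 0.0094, and adjusted p = 0.53 with an estimated correlation). RBM15B was at 1.03 (SE 0.09) and METTL16 at 0.77 (SE 0.12).

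The other lists that passed in U87 MG had fewer called members. In the ATF4 target list 6 of 31 members fell and 2 rose, as they did adjusted over the list alone, with a median of -0.34 (adjusted p = 0.009, and adjusted p = 0.71 with an estimated correlation). STC2 was at -1.13 (SE 0.13) and DDIT4 at -1.19 (SE 0.16). In the unfolded protein response list 6 of 25 fell and 1 rose, as they did adjusted over the list alone, with a median of -0.21 (adjusted p = 0.0059, and adjusted p = 0.61 with an estimated correlation). HSP90B1 was at -0.78 (SE 0.10) and CRELD2 at -0.60 (SE 0.10). Of 27 histone genes H4C3 fell, by 0.88, also when adjusted over the list alone, and the list's median was -0.38 (adjusted p = 0.0051, and adjusted p = 0.53 with an estimated correlation). Of 47 ribosomal protein genes RPL10A fell, by 0.30, or 0 members adjusted over the list alone, and the median was -0.12 (adjusted p = 0.0059, and adjusted p = 0.71 with an estimated correlation). MT-CYB rose by 0.54 among 13 mitochondrially encoded mRNAs, or 0 adjusted over the list alone, with a median of 0.16 (adjusted p = 0.034, and adjusted p = 0.71 with an estimated correlation). Of 25 cholesterol genes NSDHL (0.94, SE 0.12) and LSS (0.71, SE 0.19) rose and PMVK fell by 0.37, or 1 and 0 adjusted over the list alone, with a median of 0.24 (adjusted p = 0.05, and adjusted p = 0.8 with an estimated correlation). Signs of median, mean and test differed for oxidative phosphorylation (-0.01, 0.01, up), NRF2 targets (-0.06, -0.03, up) and neuron markers (-0.07, 0.02, down), which did not pass.

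Part of these results in U87 MG was lost when 1 library was left out, which also lowers power. The count of changed genes was 1208 without replicate 2 in DMSO, 890 without replicate 2 in STM2457 and 1469 without replicate 3 in STM2457. ITGA11 lost its call without replicate 2 in STM2457 (adjusted p = 0.051), PPL without replicate 2 of either group (highest adjusted p 0.061), and H4C3 without replicate 2 in DMSO (0.055). PMS2, PMVK and RPL10A lost theirs without any 1 of the 6 libraries (0.16, 0.17 and 0.14), LSS without any 1 except replicate 1 in DMSO (0.09), and MT-CYB without replicate 2 or 3 in DMSO or 1 or 3 in STM2457 (0.15). The cholesterol list lost its call without replicate 3 in DMSO or replicate 1 in STM2457 (highest adjusted p 0.75), and with every library scaled to the same total (0.074) or upper quartile (0.054). The ribosomal list lost it at equal totals (0.069), the mitochondrial list without replicate 2 in DMSO or 1 or 3 in STM2457 (0.18), the ATF4 list without replicate 1 in DMSO or 2 in STM2457 (0.13), and the unfolded protein response list without replicate 2 in STM2457 (0.053). Without 1 library the median was -0.61 to -0.27 for the matrix, -0.56 to -0.18 for the ATF4, -0.39 to -0.16 for the S phase, 0.13 to 0.24 for the m6A, 0.20 to 0.32 for the p53 and 0.11 to 0.27 for the mitochondrial list.

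In U87-R, STM2457 lowered MGMT from 1328 ± 390 to 646.4 ± 147 normalized counts, a fall by 1.02 (SE 0.25; n = 3; adjusted p = 0.028). The gene DHRS2 rose by 3.34 (SE 0.45), MEGF6 by 3.73 (SE 0.36), CRYM by 2.7 (SE 0.47), KCP by 2.60 (SE 0.64) and the presynaptic gene PCLO by 2.58 (SE 0.36), and the histone gene H3C14, which has near-identical copies, by 5.58 (SE 1.37). DMBT1 was at -4.79 (SE 0.38), the metalloproteinase inhibitor gene TIMP3 at -2.98 (SE 0.17), the sialyltransferase gene ST8SIA5 at -2.88 (SE 0.26), VCAM1 at -2.72 (SE 0.25), PPL at -2.65 (SE 0.18) and CLEC3B at -2.63 (SE 0.31). YTHDF2 rose by 0.79 (SE 0.09; adjusted p = 0.0017) and PMS2 by 0.68 (SE 0.17; adjusted p = 0.028). METTL3, at 0.15 (SE 0.13; adjusted p = 0.5), did not pass, nor did MSH6, at -0.19.

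In U87-R 2373 of 16185 genes changed, 1370 higher and 1003 lower, with equal totals 1683 and 869, and with equal upper quartiles 1237 and 1229. The replicate numbers paired these libraries, with correlations of 0.114 to 0.298, and the blocked fit called 4796. Of 25 lists, 8 passed. Of 30 hypoxia and glycolysis genes 26 fell, or 28 adjusted over the list alone, with a median of -0.83 (camera adjusted p = 3.3e-17, and adjusted p = 0.37 with an estimated correlation). The collagen hydroxylase gene P4HA1 was at -1.31 (SE 0.11), VEGFA at -0.85 (SE 0.11) and the carbonic anhydrase gene CA9 at -2.45 (SE 0.36). Of 25 cholesterol genes 13 rose, or 14 adjusted over the list alone, with a median of 0.46 (adjusted p = 9.2e-06, and adjusted p = 0.37 with an estimated correlation). LSS was at 0.78 (SE 0.09) and DHCR7 at 0.82 (SE 0.11). Of 32 G2 and M phase genes 10 fell and 1 rose, or 12 and 1 adjusted over the list alone, with a median of -0.36 (adjusted p = 9.2e-06, and adjusted p = 0.37 with an estimated correlation). ANLN was at -0.83 (SE 0.13) and KIF11 at -0.61 (SE 0.11). Of 40 matrix and mesenchymal genes 16 fell and 6 rose, or 21 and 7 adjusted over the list alone, with a median of -0.45 (adjusted p = 0.00029, and adjusted p = 0.49 with an estimated correlation). COL1A1 was at -1.89 (SE 0.17). Of 29 p53 targets 9 rose, while 13 rose and 1 fell adjusted over the list alone, with a median of 0.37 (adjusted p = 0.00056, and adjusted p = 0.37 with an estimated correlation). TP53I3 was at 1.59 (SE 0.20) and GDF15 at 1.98 (SE 0.34).

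Of 47 ribosomal protein genes in U87-R 6 fell, also when adjusted over the list alone, with a median of -0.20 (camera adjusted p = 1.3e-05, and adjusted p = 0.49 with an estimated correlation). RPS3A was at -0.39 (SE 0.08) and RPS7 at -0.38 (SE 0.09). Of 13 mitochondrially encoded mRNAs 3 rose, or 4 adjusted over the list alone, with a median of 0.19 (adjusted p = 0.0045, and adjusted p = 0.64 with an estimated correlation). MT-ND6 was at 0.59 (SE 0.09) and MT-CYB at 0.67 (SE 0.11). Of 25 unfolded protein response genes 6 fell and 1 rose, as they did adjusted over the list alone, with a median of -0.12 (adjusted p = 0.014, and adjusted p = 0.49 with an estimated correlation). HSP90B1 was at -0.96 (SE 0.18) and SDF2L1 at 0.69 (SE 0.14). Signs of median, mean and test differed for oxidative phosphorylation (-0.01, 0.01, down), histones (0.06, 0.02, down) and endothelial markers (-0.12, -0.01, up), which did not pass. The count of changed genes was 1361 without replicate 1 and 1142 without replicate 2 in DMSO, and 1500 without replicate 1 and 884 without replicate 2 in STM2457. MGMT and RPS7 lost their calls without replicate 1 or 2 in DMSO or replicate 2 in STM2457 (highest adjusted p 0.10 and 0.097), MGMT also without replicate 3 and RPS7 without replicate 1 in STM2457, and RPS3A without replicate 1 or 2 in DMSO or 2 in STM2457 (0.076). KCP and PMS2 lost theirs without replicate 2 in DMSO or 1 or 2 in STM2457 (0.099 and 0.096), SDF2L1 without replicate 2 of either group (0.07), and H3C14 without any 1 library except replicate 3 in DMSO (0.09). The unfolded protein response list lost its call without replicate 1 of either group (highest adjusted p 0.084). Without 1 library its median was -0.23 to -0.10, that of p53 targets 0.15 to 0.42 and that of the mitochondrial list 0.10 to 0.26.

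In LN229, the largest rises after STM2457 were in DCT, a melanin synthesis gene, from 41.4 ± 15.1 to 5288 ± 2840 (SD, n = 3; adjusted p = 2.3e-05), in PHACTR1 by 6.23 (SE 0.26), the calcium-binding protein gene NECAB2 by 6.22 (SE 0.81), FAM167B by 6.12 (SE 0.31) and the angiotensin precursor gene AGT by 5.2 (SE 0.47). UTP14C, which has a near-identical copy, rose by 5.69 (SE 1.71). The imprinted noncoding RNA H19 went from 5454 ± 1320 to 48.4 ± 30.8, with a log2 change of -7.02. Falls were also found in the myelin gene MAG (-5.04, SE 0.22), the potassium channel gene KCNA2 (-5.39, SE 0.27), ST8SIA5 (-5.28, SE 0.31) and the lipase gene LPL (-4.59, SE 0.23). YTHDF2 (ENSG00000198492) rose by 0.86 (SE 0.07; adjusted p = 4.6e-05), and the demethylase genes FTO and ALKBH5 rose by 0.28 (SE 0.08) and 0.29 (SE 0.08). MPG was at -0.50 (SE 0.11), MDM2 at -0.55 (SE 0.09), CDKN1A at -0.36 (SE 0.11) and SOX2 at -0.44 (SE 0.12). METTL3, at -0.04 (SE 0.10; adjusted p = 0.74), MSH6 at -0.07 and PMS2 at 0.01 did not pass, and MGMT was not listed in this table.

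In LN229 8506 of 17107 genes changed, 4474 higher and 4032 lower, with equal upper quartiles 4080 and 4623, and with equal totals 4267 and 4323. Of 25 lists, 14 passed, all with an adjusted p of 0.65 to 0.7 with an estimated correlation. Of 32 G2 and M phase genes 29 fell, also when adjusted over the list alone, with a median of -1.09 (camera adjusted p = 5e-08). HMMR was at -1.95 (SE 0.25) and BUB1 at -1.20 (SE 0.15). Of 28 S phase genes 21 fell and 1 rose, as they did adjusted over the list alone, with a median of -0.83 (adjusted p = 7.1e-05). GINS4 was at -1.21 (SE 0.12) and CDC45 at -1.61 (SE 0.17). Of 26 glutathione and NRF2 targets 20 rose, or 22 adjusted over the list alone, with a median of 0.94 (adjusted p = 3.3e-06). The heme oxygenase gene HMOX1 was at 2.85 (SE 0.11) and OSGIN1 at 2.84 (SE 0.33). Of 31 ATF4 targets 18 rose and 4 fell, as they did adjusted over the list alone, with a median of 0.66 (adjusted p = 0.0025). ATF3 was at 2.89 (SE 0.13) and SLC7A5 at 2.63 (SE 0.21). Of 38 interferon response genes 15 rose and 1 fell, or 14 and 1 adjusted over the list alone, with a median of 1.25 (adjusted p = 0.002). ISG20 was at 1.92 (SE 0.27) and STAT2 at 0.91 (SE 0.19). Of 24 cholesterol genes 16 rose and 1 fell, or 17 and 1 adjusted over the list alone, with a median of 0.53 (adjusted p = 0.00065). NSDHL was at 1.25 (SE 0.11) and INSIG1 at 1.53 (SE 0.14). Of 30 hypoxia and glycolysis genes 11 rose and 2 fell, as they did adjusted over the list alone, with a median of 0.20 (adjusted p = 0.023). SLC2A3 was at 1.53 (SE 0.10), ENO2 at 1.47 (SE 0.10) and GAPDH, which has many pseudogenes, at -0.65 (SE 0.14).

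Repair lists had negative medians in LN229. Of 27 homologous recombination and Fanconi anemia genes 18 fell and 3 rose, or 19 and 3 adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.0035, and adjusted p = 0.65 with an estimated correlation). FANCL was at -1.56 (SE 0.10), FANCA at -1.41 (SE 0.14) and FANCF at 1.17 (SE 0.11). Of 12 mismatch repair genes 8 fell, also when adjusted over the list alone, with a median of -0.48, among them LIG1 at -1.06 (SE 0.21; for the list, camera adjusted p = 0.012, and adjusted p = 0.65 with an estimated correlation). Of 20 direct reversal and base excision genes 10 fell and 2 rose, as they did adjusted over the list alone, with a median of -0.45 (adjusted p = 0.023, and adjusted p = 0.65 with an estimated correlation). PARP2 was at -1.05 (SE 0.10) and FEN1 at 1.25 (SE 0.20). Of 47 ribosomal protein genes 18 fell, or 16 adjusted over the list alone, with a median of -0.34 (adjusted p = 0.00024, and adjusted p = 0.7 with an estimated correlation). RPL8 was at -0.58 (SE 0.13) and RPS2 at -0.68 (SE 0.15). Of 39 nuclear oxidative phosphorylation genes 17 fell and 2 rose, as they did adjusted over the list alone, with a median of -0.19 (adjusted p = 0.00095, and adjusted p = 0.65 with an estimated correlation). SDHC was at -0.66 (SE 0.07) and UQCRFS1 at 0.97 (SE 0.07). Of 25 unfolded protein response genes 10 fell and 2 rose, as they did adjusted over the list alone, with a median of -0.20 (adjusted p = 0.016, and adjusted p = 0.65 with an estimated correlation). HSP90B1 was at -1.76 (SE 0.10) and DNAJB9 at 0.90 (SE 0.14). Of 6 endothelial marker genes 5 rose, also when adjusted over the list alone, with a median of 1.56 (adjusted p = 0.011, and adjusted p = 0.65 with an estimated correlation). ESAM was at 2.64 (SE 0.22) and KDR at 2.87 (SE 0.44). Immediate early genes, with a median of 0, a mean of -0.06 and an upward test, did not pass.

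Leaving out 1 LN229 library at a time gave 6591 to 8621 changed genes. The median was then 0.50 to 1.65 for the interferon, -0.99 to -0.49 for the S phase, -0.63 to -0.36 for the homologous recombination, -0.44 to -0.17 for the ribosomal, -0.31 to -0.12 for the unfolded protein response and 0.09 to 0.29 for the hypoxia list. The hypoxia list lost its call without replicate 2 in DMSO or in STM2457 (highest adjusted p 0.097), and the base excision list without replicate 2 in STM2457 (adjusted p = 0.051). FTO lost its call without replicate 2 or 3 in DMSO or 3 in STM2457 (0.072), ALKBH5 without replicate 1 or 2 in DMSO (0.053), CDKN1A without replicate 1 in DMSO or 3 in STM2457 (0.082), SOX2 without replicate 1 or 3 in DMSO (0.068), and UTP14C without replicate 1 or 2 in DMSO or 1 or 3 in STM2457 (0.086).

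In LN229-R, DCT went from 11.5 ± 6.56 in DMSO to 2972 ± 800 after STM2457 (SD, n = 3; adjusted p = 2.1e-05), and the stress-response gene NUPR1 from 4.40 ± 5.34 to 1076 ± 652. NECAB2 rose by 6.88 (SE 0.59), FAM167B by 6.0 (SE 0.52), CEDORA by 5.90 (SE 0.57) and UTP14C by 6.26 (SE 1.82). H19 went from 9477 ± 1600 to 19.5 ± 13.5 and the fatty acid receptor gene FFAR1 from 493 ± 299 to 1.25 ± 2.17. MAG was at -6.21 (SE 0.24), KCNA2 at -6.06 (SE 0.20) and ST8SIA5 at -5.45 (SE 0.21). YTHDF2 rose by 0.76 (SE 0.11; adjusted p = 0.0014), FTO by 0.36 (SE 0.11) and ALKBH5 by 0.28 (SE 0.09). MPG was at -0.71 (SE 0.12), MDM2 at -0.74 (SE 0.12) and CDKN1A at -0.60 (SE 0.20). MGMT had 195.5 ± 8.38 in DMSO and 175 ± 13.6 after STM2457, a log2 change of -0.16 that did not pass (SE 0.16; adjusted p = 0.46), nor did METTL3, at -0.16 (SE 0.11; adjusted p = 0.29).

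In LN229-R 6591 of 17063 genes changed, 3674 higher and 2917 lower, with equal upper quartiles 3351 and 3475, and with equal totals 3655 and 2915. Correlations between like-numbered libraries were 0.102 to 0.321, and the blocked fit called 8444. Of 24 lists, 13 passed. Of 26 glutathione and NRF2 targets 22 rose, or 23 adjusted over the list alone, with a median of 1.17 (camera adjusted p = 3.9e-10, and adjusted p = 0.11 with an estimated correlation). OSGIN1 was at 3.57 (SE 0.15) and the sulfiredoxin gene SRXN1 at 2.17 (SE 0.13). The other lists had an adjusted p of 0.63 or 0.64 with an estimated correlation. Of 38 interferon response genes 24 rose, or 27 adjusted over the list alone, with a median of 1.59 (adjusted p = 5e-07). ISG20 was at 2.07 (SE 0.18) and IFIT3 at 2.51 (SE 0.33). Of 24 cholesterol genes 19 rose, also when adjusted over the list alone, with a median of 0.81 (adjusted p = 3.1e-07). LSS was at 1.85 (SE 0.10). Of 31 ATF4 targets 13 rose and 1 fell, or 14 and 1 adjusted over the list alone, with a median of 0.70 (adjusted p = 0.00035). ATF3 was at 3.02 (SE 0.17) and SLC3A2 at 1.94 (SE 0.14). Of 22 inflammatory genes 9 rose and 1 fell, as they did adjusted over the list alone, with a median of 0.58 (adjusted p = 0.038). SOD2 was at 2.54 (SE 0.25) and NFKBIA at 1.23 (SE 0.15). Of 32 G2 and M phase genes 6 fell, or 0 adjusted over the list alone, with a median of -1.24 (adjusted p = 4.6e-05). CCNB2 was at -1.43 (SE 0.44) and NDC80 at -1.59 (SE 0.50). Of 28 S phase genes 6 fell, or 0 adjusted over the list alone, with a median of -1.05 (adjusted p = 0.0026). PRIM1 was at -1.09 (SE 0.28) and MCM7 at -1.36 (SE 0.39).

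Of 47 ribosomal protein genes in LN229-R 13 fell, or 0 adjusted over the list alone, with a median of -0.52 (camera adjusted p = 8.8e-06). RPS2 was at -0.98 (SE 0.22) and RPL12 at -0.87 (SE 0.20). Of 39 oxidative phosphorylation genes 13 fell and 1 rose, as they did adjusted over the list alone, with a median of -0.26 (adjusted p = 0.00035). ATP5PO was at -0.88 (SE 0.13) and UQCRFS1 at 0.97 (SE 0.11). Of 25 unfolded protein response genes 10 fell and 2 rose, as they did adjusted over the list alone, with a median of -0.32 (adjusted p = 0.0029). CRELD2 was at -1.60 (SE 0.11) and HSP90B1 at -2.23 (SE 0.17). Base excision genes had a median of -0.37, with 9 of 21 falling and 1 rising, as they did adjusted over the list alone, and TDG at -0.77 (SE 0.12; for the list, camera adjusted p = 0.03, and adjusted p = 0.63 with an estimated correlation). Mismatch repair genes had a median of -0.58, with 4 of 12 falling, also when adjusted over the list alone, among them MSH3 at -0.83 (SE 0.14; for the list, camera adjusted p = 0.038, and adjusted p = 0.63 with an estimated correlation). The homologous recombination and Fanconi list had a median of -0.51, with 5 of 27 falling and 1 rising, or 4 and 1 adjusted over the list alone, FANCL at -1.41 (SE 0.13) and FANCF at 1.20 (SE 0.11; for the list, camera adjusted p = 0.046, and adjusted p = 0.64 with an estimated correlation). The hypoxia list missed the threshold, with a median of 0.17 and 9 members rising and 3 falling (adjusted p = 0.052), and passed with the block (adjusted p = 0.031) and at equal totals (adjusted p = 0.048). Signs of median, mean and test differed for p53 targets (0.06, 0.07, down), immediate early genes (0.10, -0.06, up) and neuron markers (-0.18, 0.06, down), which did not pass.

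The count of changed genes in LN229-R was 4364 without replicate 3 in DMSO. Without replicate 1 or 3 in DMSO the calls of CCNB2, PRIM1 and MCM7 were lost (highest adjusted p 0.11, 0.068 and 0.084), and NDC80 was lost without either of these or replicate 3 in STM2457 (0.11). ALKBH5 lost its call without any 1 of the 6 libraries (0.14), FTO without any 1 except replicate 2 in STM2457 (0.12), UTP14C without any 1 except replicate 2 in DMSO (0.097), and CDKN1A without any 1 in DMSO or replicate 3 in STM2457 (0.12). The mismatch repair, homologous recombination and inflammatory lists lost their calls without replicate 1 or 3 in DMSO or replicate 2 in STM2457 (highest adjusted p 0.089, 0.22 and 0.089), and the S phase list without replicate 2 in STM2457 (0.06). The hypoxia list passed without replicate 1 in DMSO (adjusted p = 0.034) or replicate 2 in STM2457 (0.0073). Without 1 library the median was -1.59 to -0.60 for the G2 and M phase, -1.28 to -0.37 for the S phase, -0.72 to -0.16 for the homologous recombination, -0.70 to -0.36 for the mismatch repair, 0.38 to 0.86 for the ATF4, 1.02 to 1.86 for the interferon and 0.53 to 1.03 for the inflammatory list. Replicate 2 in DMSO stood apart, with 3.27% of normalized counts in ribosomal protein genes against 2.01 and 2.13% in the other DMSO libraries, and without it the ribosomal protein median was -0.29.

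**Figure D2:**
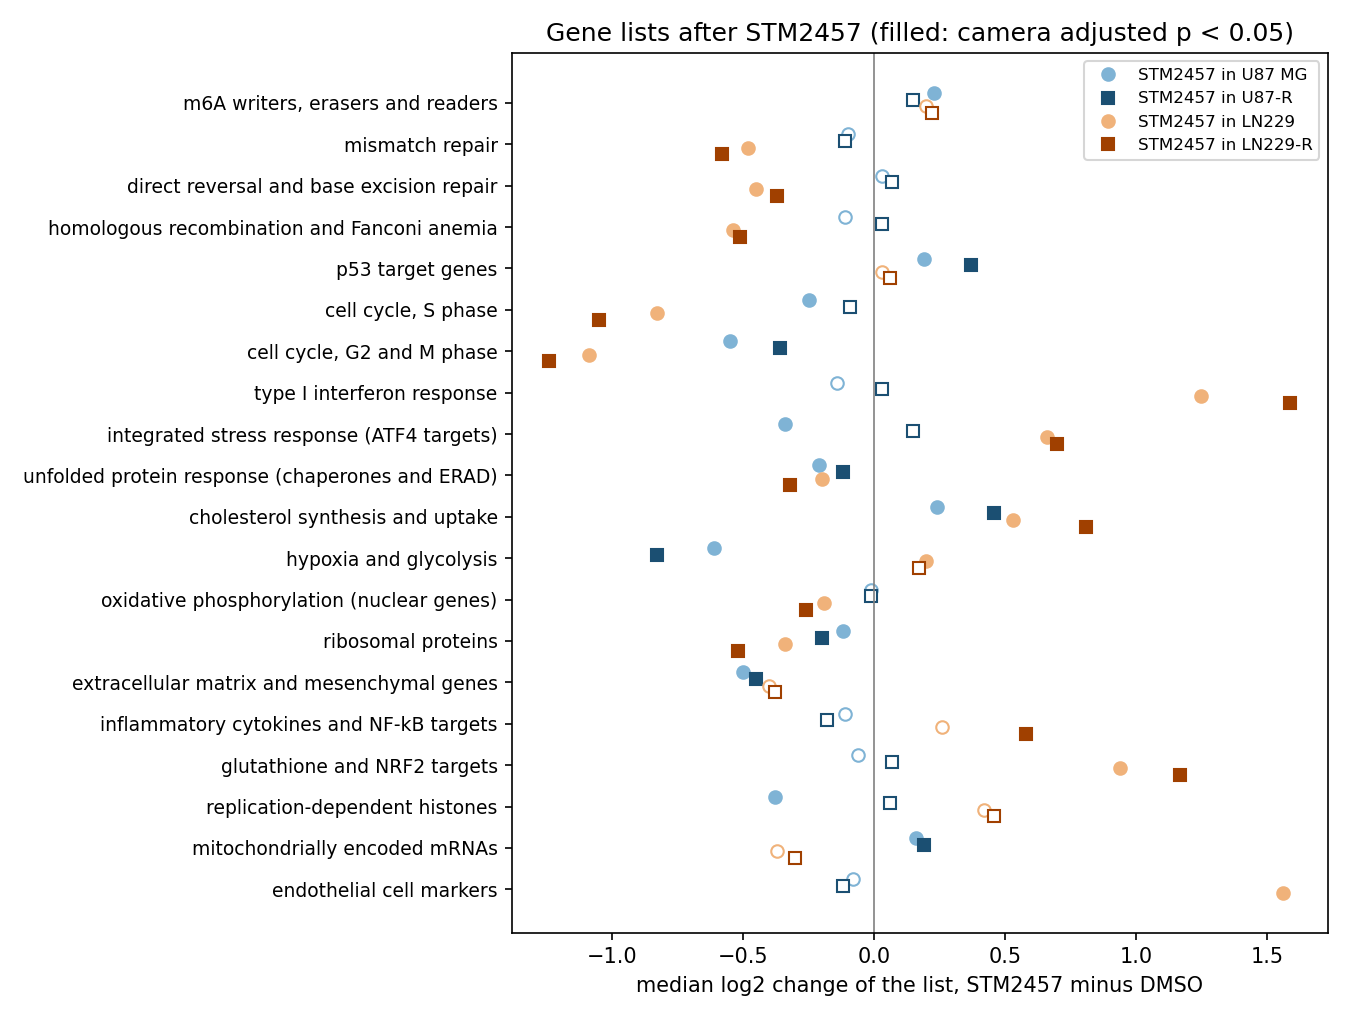
Median log2 change of each gene list after STM2457, with 1 marker per line and filled markers for lists with a camera adjusted p under 0.05. The hypoxia and glycolysis medians are -0.61 in U87 MG and -0.83 in U87-R but 0.20 in LN229 and 0.17 in LN229-R.

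The 6 remaining lists passed in no comparison. Immediate early genes had medians of -0.11 and 0.16 between resistant and parental cells in U87 and LN229, and after STM2457 -0.10, -0.12, 0 and 0.10 in U87 MG, U87-R, LN229 and LN229-R. Glioma stem and astrocyte genes had medians of 0.24, -0.05, -0.32, -0.25, -0.44 and -0.21 in the same order. Neuron markers had medians of -0.11, 0.15, -0.07, -0.11, -0.15 and -0.18. Oligodendrocyte lineage markers had enough measured members in the LN229 family, with medians of -0.10 between the labelled lines, -0.16 in LN229 and -0.48 in LN229-R. Of 5 measured epithelial markers in U87-R, 1 fell after STM2457, with a median of -1.04 (adjusted p = 0.25), and elsewhere 3 or 4 members were measured. Immune cell markers had 2 or 3 measured members and were not tested.

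The response to STM2457 was shared between parental and resistant cells. In U87 MG and U87-R 1335 genes changed in the same direction, 808 higher and 527 lower, against 167 expected from the counts, and 1 changed in opposite directions (15680 genes). In LN229 and LN229-R 5627 changed in the same direction, 3204 higher and 2423 lower, against 1640 expected, and 4 in opposite directions. Across genes, which are not independent replicates, the log2 changes of the paired lines had Pearson's r of 0.648 and 0.889 and Spearman's rho of 0.708 and 0.898. Across backgrounds, 1322 genes changed alike and 139 oppositely in U87 MG and LN229 (expected alike 529, r 0.384), and 1182 alike and 140 oppositely in U87-R and LN229-R (expected alike 428, r 0.367). The U87 MG and U87-R overlap was 649 without replicate 2 of U87-R in STM2457, 802 without its replicate 2 in DMSO, and 704 and 865 without replicate 2 of U87 MG in STM2457 and in DMSO.

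In all 4 lines 742 of 13363 genes changed in the same direction, 562 higher and 180 lower. The product of the 4 called shares gives 8.84, as if the lines were independent. The changes of each resistant line overlap with those of its parental line, so 8.84 is too low as an expected number. IL24 rose by 2.58, 2.02, 5.37 and 3.09 in U87 MG, U87-R, LN229 and LN229-R (SE 0.42, 0.51, 0.58 and 0.48). ACP5, a lysosomal acid phosphatase gene, rose by 2.27, 2.41, 3.48 and 4.69 (SE 0.35, 0.26, 0.40 and 0.18), CCN3 by 0.88, 0.93, 3.64 and 4.94, and MFSD5 by 1.64, 1.85, 3.17 and 3.46. RIMBP3B, a gene with near-identical copies, rose by 1.53, 2.12, 3.16 and 3.43. Falls were found in ST8SIA5 (-2.36, -2.88, -5.28 and -5.45, with SE 0.29, 0.26, 0.31 and 0.21) and ITGA11 (-3.73, -3.84, -1.43 and -3.67). COL1A2 was at -2.64, -1.97, -2.32 and -4.0, the IGF-binding protein gene IGFBP3 at -1.94, -2.19, -3.1 and -3.52, and the immediate early gene EGR1 at -1.15, -0.97, -3.32 and -4.04. The count was 375 without replicate 2 of U87-R in STM2457, 464 without its replicate 2 in DMSO and 406 without replicate 2 of U87 MG in STM2457. In U87-R IL24 lost its call without replicate 1 or 2 in STM2457 (highest adjusted p 0.12), and CCN3 and RIMBP3B without replicate 2 in STM2457 (0.056 and 0.064). In U87 MG CCN3 lost it without replicate 2 or 3 in DMSO or 1 or 2 in STM2457 (0.099), and RIMBP3B without replicate 2 in DMSO or any 1 in STM2457 (0.10). COL1A2 lost its call in LN229 without replicate 1 in DMSO (0.053).

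**Figure D3:**
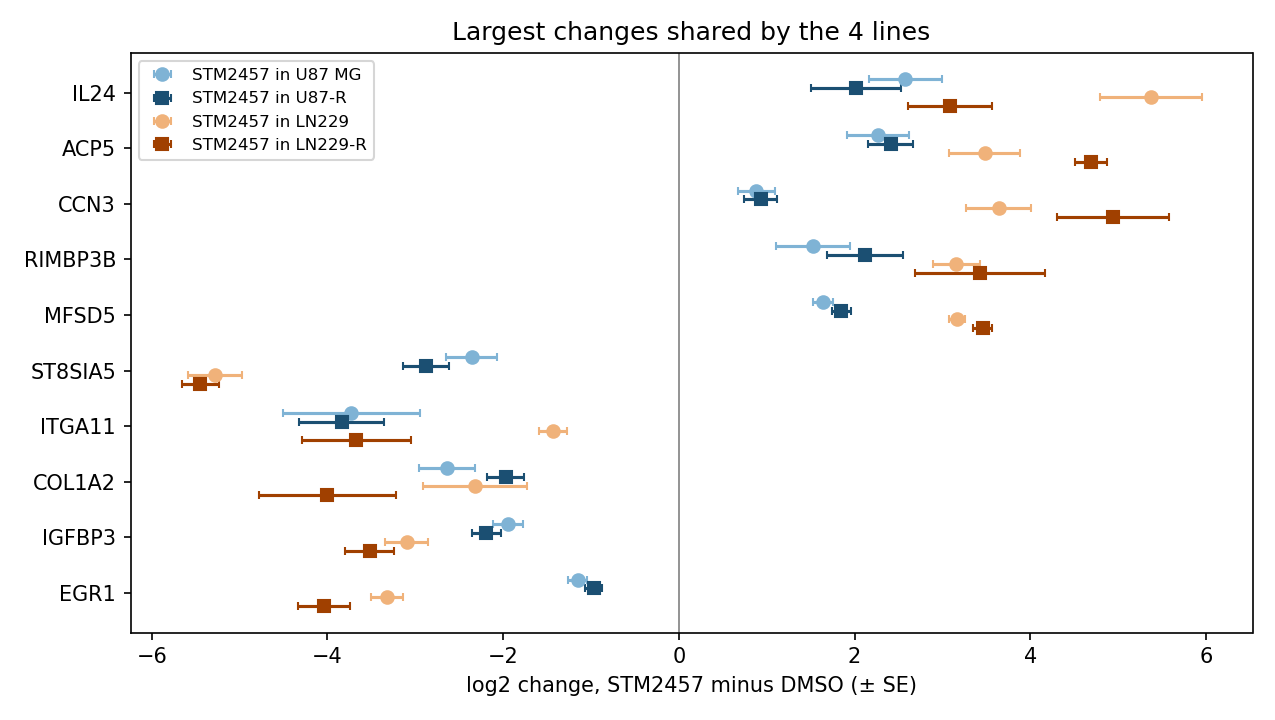
Log2 change after STM2457, with its standard error, of the 5 largest rises and 5 largest falls by mean log2 change among the 742 genes that changed in the same direction in all 4 lines. ST8SIA5 had log2 changes of -2.36 and -2.88 in the U87 lines and of -5.28 and -5.45 in the LN229 lines.

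Whether parental and resistant cells respond differently was tested on the difference itself. In U87-R against U87 MG 0 of 16403 genes passed with limma, 617 (3.8%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.058, for the growth factor gene FGF14 (2.71 in U87-R, -1.64 in U87 MG). Without replicate 3 of U87 MG in DMSO or replicate 1 of U87-R in STM2457 FGF14 passed (lowest adjusted p 0.031). In LN229-R against LN229 1 of 17072 passed, the multi-copy ribosomal RNA gene RNA5-8SN2, which polyadenylated libraries measure poorly. Its difference of -14.02 (SE 0.70; adjusted p = 2.2e-06) set groups at 0 in all libraries against groups of up to 138 and 360 normalized counts. In the same test 709 genes had an unadjusted p under 0.05, and GTF2A1L, AQP1, TINAGL1 and ANKS1A followed with an adjusted p of 0.066. AQP1 passed without replicate 2 of LN229-R in DMSO (0.033), and TINAGL1 without its replicate 2 in STM2457 (0.014). FGF14 and RNA5-8SN2 were named because they stood at the top of these tests. At list level 7 of 24 lists passed camera in U87-R against U87 MG with 0 members passing (adjusted p 1.3e-07 to 0.042, and 0.71 with an estimated correlation). ATF4 targets (median difference 0.39), histone (0.45), cholesterol (0.21), S phase (0.14) and G2 and M phase genes (0.16) were shifted up, and hypoxia (-0.16) and ribosomal protein genes (-0.07) down. In LN229-R against LN229 4 of 26 passed with 0 members passing (adjusted p 0.00015 to 0.047, and 0.85 to 0.98 with an estimated correlation). Cholesterol genes (0.24) were shifted up, and unfolded protein response (-0.16), ribosomal protein (-0.20) and p53 target genes (-0.15) down.

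Between backgrounds the differences were wide, in tests added after the data were examined. Of 16075 genes 2653 responded differently to STM2457 in LN229 than in U87 MG, 1630 higher and 1023 lower, and of 15848 genes 2041 in LN229-R than in U87-R, 1351 higher and 690 lower. The lactate carrier gene SLC16A3, chosen after its values were seen, rose by 2.32 in LN229 and fell by 1.10 in U87 MG. In the hypoxia list 20 members were higher in the LN229 response than in that of U87 MG, with a median difference of 1.03 (camera adjusted p = 2.9e-14, and adjusted p = 0.31 with an estimated correlation). Between LN229-R and U87-R 17 were higher, with a median of 1.29 (adjusted p = 1.1e-13, and adjusted p = 0.35 with an estimated correlation). NRF2 targets differed by medians of 1.12, with 13 members higher (adjusted p = 4.8e-10, and adjusted p = 0.39 with an estimated correlation), and 1.03, with 17 higher (adjusted p = 3.3e-13, and adjusted p = 0.13 with an estimated correlation). Interferon genes differed by medians of 1.12, with 2 members higher (adjusted p = 0.00015, and adjusted p = 0.58 with an estimated correlation), and 1.5, with 10 higher (adjusted p = 3.9e-09, and adjusted p = 0.41 with an estimated correlation). In all, 15 of 25 lists passed camera in LN229 against U87 MG, 7 shifted up and 8 down, and 17 of 26 in LN229-R against U87-R, 7 up and 10 down, and 0 with an estimated correlation. ATF4 targets were shifted up by medians of 0.70 and 0.49, with 13 and 9 members higher. Shifted down in both were G2 and M phase (-0.52 and -0.83), S phase (-0.42 and -0.74), homologous recombination (-0.44 and -0.55), base excision (-0.39 and -0.50), mismatch repair (-0.39 and -0.58), oxidative phosphorylation (-0.18 and -0.25), ribosomal protein (-0.25 and -0.34) and mitochondrially encoded genes (-0.54 and -0.53). Library kit, RNA input, medium and serum differed between the backgrounds as well.

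Resistance-associated changes were compared between backgrounds. With the libraries as labelled, 56 of 13890 genes changed alike in U87-R and in the libraries labelled LN229-R, 43 higher and 13 lower, against 27.6 expected, and 56 changed oppositely (r across genes 0.004). Fisher's exact test (two-sided, p = 2.2e-16) covers the 112 genes called in both in either direction, and does not show that they changed alike. With the LN229 names exchanged these 2 sets trade places, 26 higher and 30 lower against 22.8 expected. Alike as labelled were MAGEA11 (6.15 in U87, 7.34 in LN229), the complement regulator gene CSMD1 (5.91 and 4.25), EFS (4.30 and 5.18), the collagen gene COL5A3 (3.07 and 6.16) and ZNF208 (4.41 and 4.59), and lower in both were ARAP2 (-4.66 and -0.61), the ephrin receptor gene EPHA3 (-4.24 and -0.61), UNC5C (-3.91 and -0.38), PCDH10 (-1.60 and -1.54) and TIMP3 (-1.65 and -0.72). Opposite as labelled, and alike with exchanged names, were MGMT, IGFBP2 (5.89 and -0.77), the receptor kinase gene KIT (5.08 and -1.40), SCARA5 (3.26 and -2.88) and LZTS1 (4.43 and -0.62), and in the other direction CPZ (-5.75 and 5.67), TMEM200C (-5.73 and 2.32) and CACNG8 (-3.05 and 3.23). In a test of the difference 1358 of 15971 genes differed, 722 higher and 636 lower in the LN229 family as labelled, and 1172 with exchanged names, 367 higher and 805 lower. As labelled, 8 of 26 lists passed camera in that test, 6 shifted up and 2 down, and with exchanged names 1 passed, shifted down. With an estimated correlation 0 passed in either reading.

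Calls in this overlap were often lost when 1 library was left out, which also lowers power. The overlap was 25 without replicate 2 of U87 MG, 32 without replicate 2 of U87-R, and 31, 37 and 34 without replicate 1, 2 or 3 of the libraries labelled LN229-R. The test of the difference gave 874 genes without replicate 3 of the libraries labelled LN229-R. In U87, EFS lost its call without any 1 library except replicate 3 of U87 MG (highest adjusted p 0.099), ARAP2 without replicate 1 or 2 of U87 MG or 2 or 3 of U87-R (0.18), PCDH10 without replicate 1 or 2 of either line (0.072), EPHA3 without any 1 of U87 MG (0.064) and UNC5C without replicate 3 of U87 MG (0.054). In LN229, EPHA3 and UNC5C lost theirs without any 1 library except replicate 2 labelled LN229 (0.15 and 0.14), ARAP2 without replicate 1 labelled LN229 or any 1 labelled LN229-R (0.11), IGFBP2 without replicate 3 labelled LN229 or 1 or 3 labelled LN229-R (0.072), and LZTS1 without replicate 1 or 2 labelled LN229-R (0.068).

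Whether STM2457 moves resistance-associated genes back towards the parental level was asked with the same control libraries in both comparisons. In U87-R 126 genes changed oppositely with resistance and with STM2457, 105 of them higher in resistant cells, against 45.1 expected, and 38 changed alike (15856 genes; r across genes -0.259, covariance -0.104). Examples are ADAMTSL2 (4.13 with resistance, -3.57 with STM2457), SCARA5 (3.26 and -4.01), AGXT (4.79 and -2.84), PROM2 (3.55 and -2.84) and SNTG2 (4.33 and -2.59). MGMT (9.42 and -1.02) was also among the 126. Its STM2457 call was lost without single libraries, as given above, and 646 normalized counts remained, against 0.7 in U87 MG. In 100 simulations with shared controls and no effect the mean r was -0.497, from -0.559 to -0.442, and the covariance was -0.0634. The number of opposite calls was 0. Without effects hardly any gene passes, so this 0 cannot say how many of the 126 come from shared controls. The observed r was weaker than in any simulation and the covariance larger in size, so r alone is no evidence of a return towards the parental level. In LN229-R as labelled 169 genes changed oppositely and 546 alike, against 264 expected opposite (16587 genes; r 0.31, covariance 0.138). This pairing joins tables whose control libraries carry different names, so it is right under neither reading of the conflict. ITGA11 (2.62 and -3.67), RBPMS2 (2.52 and -2.24) and GRIK3 (2.03 and -4.77) were among the 169. If the parental against resistant table is wrong, 546 genes changed oppositely against 269 expected and 169 alike, among the opposite ones CSMD1 (-4.25 and 4.06), the cytochrome gene CYP4F11 (-3.73 and 5.15), CCN3 (-3.25 and 4.94) and the complement protease gene C1S (-3.24 and 5.60). If the treatment tables are wrong, resistance pairs with the table named LN229, and 322 changed oppositely against 386 expected and 555 alike (16547 genes; r 0.043, covariance 0.0239). The simulated covariance was 0.0489 as labelled, and -0.0488 and -0.0407 in these 2 readings. Whether opposite changes exceed the expected number in LN229-R thus depends on which table is wrong. With 3 shared control libraries, part of an excess may come from them.

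The counts of opposite changes depended on single libraries. In U87-R the count was 72, 44 and 60 without replicate 1, 2 or 3 in DMSO, 71 without replicate 2 in STM2457 and 57 without replicate 2 of U87 MG. In LN229-R as labelled it was 32, 51 and 31 without replicate 1, 2 or 3 of LN229-R in DMSO, and 109, 397 and 78 without replicate 1, 2 or 3 of LN229 in DMSO. SCARA5 lost its STM2457 call in U87-R without replicate 1 or 2 in DMSO (highest adjusted p 0.063), AGXT without any 1 in DMSO or replicate 2 in STM2457 (0.082), and PROM2 without any 1 except replicate 3 in STM2457 (0.073). ADAMTSL2 lost its resistance call without replicate 2 of U87-R (0.05), and PROM2 without any 1 of U87-R or replicate 2 of U87 MG (0.075). In LN229-R ITGA11 lost its resistance call without replicate 3 labelled LN229 or any 1 labelled LN229-R (0.11), GRIK3 without any 1 labelled LN229-R (0.099), CCN3 without replicate 1 or 3 labelled LN229-R (0.092), and RBPMS2 its STM2457 call without replicate 2 or 3 in DMSO (0.066).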

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

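The tests of the LN229 names, of the response size, of the list splits and of STM2457 effects between backgrounds were chosen only after the result was seen. STM2457 effects in LN229-R and LN229 differed in 1 gene, RNA5-8SN2 (-14.02), an rRNA gene with identical copies that the treatment tables list at 0 in LN229 DMSO and LN229-R STM2457, while RNA5-8SN1 and RNA5-8SN3 are at 0 in LN229 STM2457. Resistance effects differed between LN229 as labelled and U87 in 1358 genes, led by MGMT (-17.06), SLITRK5 (6.99), IGFBP2 (-6.66), ZNF570 (-6.85) and TMPRSS15 (7.64), of which MGMT, SLITRK5 and ZNF570 had a group listed at 0. With exchanged names MGMT did not pass (-1.78, adjusted p = 0.11), and SLITRK5 led at -5.99. STM2457 effects differed between LN229 and U87 MG in 2653 genes, led by RNA5-8SN2 (7.38), PHACTR1 (5.88), DUSP3 (1.72) and SLC16A3 (3.41). Between LN229-R and U87-R they differed in 2041 genes, led by MLPH (3.42), PRUNE2 (5.50), CSF1 (2.19) and GTF2H2B (7.42), a multi-copy gene listed at 0 in LN229-R DMSO. Each was singled out because a test of the difference between 2 effects passed.

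The parental and resistant LN229 control libraries changed names between tables. In 6 of 6 columns of the parental against resistant table the closest control library carried the other line's name, which is what labels exchanged in part of the tables would give. If that table is the wrong one, LN229-R cells express MGMT, at a mean of 198.6 in the columns labelled LN229 there. Resistance may arise without MGMT, so which table is wrong cannot be told apart from these data. An exchange in that table would turn every LN229 resistance direction and leave drug directions unchanged, and one in the treatment tables would move each drug effect to the other LN229 line. No biological explanation was tested, since no cell state carries 1 library's values to another name.

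More genes changed after STM2457 in the LN229 lines than in the U87 lines. Lower noise alone was excluded, since the SD of effects with the noise taken out was at least 0.732 in the LN229 lines with any 1 replicate left out and at most 0.473 in the U87 lines. Library kit, medium and serum cannot be told apart from the background, because 0 kits were used in both. A stronger response of LN229 cells may be the source but stays untested.

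Other groupings of the libraries were tried for each comparison. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave as many changed genes as 1 of 10 (itself) in each comparison, with 697, 1585, 2228, 2373, 8506 and 6591 genes against a highest other of 1, 0, 2, 0, 0 and 1. As many lists passed in 7, 6, 2, 3, 3 and 1 of 10 splits, with 6, 8, 12, 8, 14 and 13 lists in the real split and a highest other of 11, 9, 12, 10, 14 and 12. Only in LN229-R after STM2457 did no other split pass as many, so passing alone does not show an effect. For differences between effects, 100 regroupings were drawn with each of 2 seeds. In U87-R against U87 MG, with 0 genes, 100 were as large with either seed (highest other 2 and 5267). In LN229-R against LN229 4 were as large with the first seed and 5 with the second (real 1, highest other 1 and 10565), and simulation gave 10 false calls, so chance is not excluded for this gene, although the first share is under 0.05. For resistance effects 1 was as large with the first seed and 2 with the second (real 1358, highest other 1172 and 1358). In LN229 against U87 MG 11 and 4 were as large (real 2653, highest other 7010 with either seed), and in LN229-R against U87-R 10 and 5 (real 2041, highest other 6057 and 2580). The large ones in these 3 tests all kept or mirrored the real split of 1 table and so carry its effect. This is a structure of the samples, so these shares cannot decide on chance. The rest gave at most 4 genes.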

How the results depend on the processing

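Exchanging the LN229 names was chosen only after the result was seen, as were the STM2457 tests between backgrounds. Of the named-gene values 7257 kept direction and side of the threshold, 493 lost and 22 gained a call, and 0 reversed; of list values 2134 kept, 143 lost, 51 gained and 2 reversed; of counts 320 stayed within 1.5 times and 107 did not. Orders below are resistance in U87 and LN229, then STM2457 in U87 MG, U87-R, LN229 and LN229-R. Without the variance trend the first 4 counts were 396, 951, 1301 and 1372. With the replicate as a block they were 1176, 2600, 4137 and 4796. Differing effects numbered 1 in U87-R against U87 MG without trend and at pseudocount 5, and 14 from separate fits; in LN229-R against LN229 they numbered 2 without trend and at pseudocount 0.5, 3 with the block and 89 from separate fits; for resistance 2071 with the block and 2330 from separate fits; in LN229-R against U87-R 3825 and 3176. For the shared resistance genes, those shared by U87 MG and U87-R, by all 4 lines, and the opposite ones in U87-R and LN229-R, the counts were 21, 622, 345, 51 and 88 without trend, 147, 2880, 1558, 363 and 422 with the block, 16, 412, 208, 25 and 25 at an adjusted p under 0.01, and 30, 301, 94, 58 and 18 at a log2 change of at least 1; for LN229 and LN229-R the last settings gave 3005 and 1970. A mean of at least 50 left 33 shared resistance genes, and opposite ones in LN229-R numbered 546 with names exchanged in the parental against resistant table and 322 with the treatment tables exchanged. Lists passing numbered 0 in all 6 comparisons with an estimated correlation, and with fry 1, 5, 6 and 7 in resistance in U87 and LN229 and STM2457 in U87 MG and LN229-R. The base excision median in LN229 resistance, 0.01, had the reverse test direction under fry (adjusted p = 0.00022), and the G2 and M phase median there ranged from -0.07 without replicate 2 labelled LN229 (adjusted p = 0.46) to 0.4. Leaving out 1 replicate gave 315 to 607, 534 to 3262, 890 to 1803, 884 to 2217, 6591 to 8621 and 4364 to 6425 changed genes, and 4 to 10, 8 to 8, 10 to 12, 7 to 11, 12 to 15 and 10 to 13 lists. Differing effects ranged from 0 to 5 (U87-R against U87 MG), 1 to 4 (LN229-R against LN229), 874 to 1550 (resistance), 1902 to 2658 (LN229 against U87 MG) and 1515 to 2002 (LN229-R against U87-R). Shared genes ranged from 25 to 79 (resistance), 649 to 1315 (U87), 3987 to 5506 (LN229) and 375 to 744 (4 lines), and opposite ones from 44 to 141 (U87-R) and 31 to 397 (LN229-R). Stricter thresholds lower counts by construction. Elsewhere counts also rose, and the cause was not tested. The alternatives with edgeR and DESeq2 were not run, because whole counts could not be recovered. The filter leaves out genes with a mean below 10, and depth limits those tested just above it.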

Other observations

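The test of lysosomal genes and that of length and GC content were chosen only after the result was seen. Rises after STM2457 included lysosomal genes, among them ACP5, CTSK (2.36 in U87 MG, 1.95 in U87-R, 1.51 in LN229, 1.18 in LN229-R) and RRAGD (1.21, 1.57, 1.97 and 2.08). ATP6V0D2 rose by 2.99 and 1.96 in the U87 lines and was not tested in the LN229 lines, while NMB, noticed with them, rose by 2.75 and 1.96 in the U87 lines and fell by 0.39 and 0.83 in the LN229 lines. A hypothesis was that STM2457 raises the lysosomal program of MiT/TFE transcription factors. It was tested on 45 lysosomal genes without those first seen. The list had a positive median and passed camera in 4 of 4 lines, with medians of 0.22, 0.31, 0.72 and 0.66 and 10, 17, 35 and 29 members rising and 1 falling in each. The adjusted p was 5.1e-05, 3.8e-07, 2.8e-11 and 8.1e-11, and 0.42, 0.13, 0.13 and 0.078 with an estimated correlation. NEU1 rose by 0.52, 0.70, 1.74 and 1.94, TPP1 by 0.87, 0.82, 1.09 and 1.48 and WIPI1 by 0.64, 0.65, 1.47 and 1.70. Between resistant and parental cells the medians were -0.05 in U87 and -0.01 in LN229 as labelled. A lysosomal program may thus respond to STM2457, but an effect of the compound unrelated to METTL3 was not tested.

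METTL3 inhibition should spare transcripts with little m6A and stabilize those with much. Sites of m6A are densest in long internal exons and final exons, away from exon junctions, so log2 changes were expected to be higher in genes with few junctions per kb. This was predicted before the data were examined. The rank correlation of log2 change and junction density was -0.229 in U87 MG, -0.18 in U87-R, -0.226 in LN229 and -0.23 in LN229-R, so the highest was -0.18, against -0.029 and -0.006 for resistance in U87 and LN229. Genes of 1 exon had medians of 0.16, 0.26, 0.41 and 0.49 in the 4 lines. With length, GC content and mean level taken out the highest was -0.2, which excludes length or GC bias as the whole cause. The pattern is consistent with loss of m6A after STM2457 at the tested value of -0.18, as a hypothesis, since m6A was not measured.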
